A study of Mus musculus with 6 samples.

How the data were processed

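Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in P19 cells, a mouse embryonal carcinoma line that forms neurons when treated with retinoic acid. The cells carried a viral construct for FLAG-tagged Lbx1, either wild-type or with a frameshift, and FLAG is a short peptide tag recognised by the anti-FLAG M2 antibody. Per the labels' protocols, cells were kept in 1 µM retinoic acid for 4 days as embryoid bodies, plated on laminin, given 12 µM cytosine arabinoside from day 6 to remove dividing cells, and collected on day 7. The 6 samples are 2 anti-FLAG immunoprecipitates of the wild-type construct, 2 of the frameshift construct, and 1 input (sonicated chromatin without immunoprecipitation) for each construct. Groups and replicate numbers were taken from the sample titles.

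The material analysed was 1 deposited peak list per construct, in narrowPeak format, with coordinates on mouse build mm9 per the file headers. Bowtie2, SAMtools 1.6 and build mm9 are named in the submitters' processing notes. The peak caller, its threshold, the use of the inputs and the way the 2 replicates of a construct entered 1 list are not given in the sources used here. Each peak has an interval, a summit, a score and a signal value. The signal value, by which the authors sorted each deposited list, is a positive number on a scale that no source states, so it was used to rank, describe and compare peaks within a list, and between lists only through ranks (the rank correlation over shared peaks, the ranks of paired peaks, and the strongest peaks of each list). A test of halved signal on the X chromosome further assumed a linear scale. The score in the deposited lists is a whole number between 830 and 1000. The lowest score, 830, is the whole-number part of −125 times the base-2 logarithm of 0.01, which is 830.48, a scale that the irreproducible discovery rate program writes in this column. Whether the authors used that program is not given in the sources used here. The columns for p and q values hold −1 throughout and were not used.

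The analysis planned before the data were examined assumed a fold enrichment and a −log10 q per peak. The deposited lists hold neither, so the signal value took the place of the fold enrichment, and the maximum score of 1000 took the place of a stricter q value. The planned location of peaks relative to genes, the gene lists, the peaks at Lbx1, and the sequence motifs need an mm9 annotation or genome. None was used here, since the gene table at hand was of another build (GRCm38) and coordinates were not converted between builds. Peaks are therefore given by position and without gene names.

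Read depth per sample is unknown, because peak lists carry no read totals. With 1 list per construct no test across replicates could be made, and no p-values are given. Intervals are 95% Wilson intervals for shares of peaks, exact (Clopper-Pearson) intervals for ratios of peak density and for shares within single windows, and percentile bootstrap intervals over 1000 draws of peaks for medians and correlations. They cover counting error only and treat peaks as independent, which neighbouring peaks are not. They say nothing of the spread between cultures or replicates.

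Peaks of one list were called shared when they overlapped a peak of the other list by at least 1 bp, and otherwise list-specific. No peak overlapped another peak of its own list. Overlap was computed with numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15 and gave the same counts as bedtools 2.31.1. Intervals came from scipy 1.17.1 and figures from matplotlib 3.10.9. A reference for the overlap was taken from 1000 circular shifts. In each, all frameshift peaks of a chromosome moved by 1 random offset within the span reached by the peaks of both lists. The shifts took no account of regional differences in copy number or mapping. Tested on simulated data with 59.99% of 7356 peaks planted as shared, the computation recovered 59.99%, and 100 shifts gave a mean overlap of 0.179% where 0.171% was expected from the peak lengths. The simulated sites were placed at random and more than 1 kb apart, so closely spaced peaks were not tested. Peak density per chromosome was the number of peaks divided by the position of the last peak end on that chromosome in either list. Windows of 1 Mb were counted by summit and compared with 1000 placements in which each chromosome's peaks were spread at random over its span. The windows, the neighbourhood distances and the X chromosome ratio were chosen after the data were examined.

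Peaks named by position follow a rule set before the data were examined: the 10 with the highest signal value among shared peaks (ranked in the wild-type list), wild-type-only peaks and frameshift-only peaks. The alternatives tried were a reciprocal overlap of at least 50%, summits within 100 bp, peaks within 1 kb counted as shared, neighbouring peaks within 500 bp merged, removal of unplaced sequences and of peaks wider than 2 kb, and removal of the top 1% of peaks from the correlation. Restriction to the maximum score, lists of equal length, the stronger part of each list, and removal of the densest windows were added after the data were examined. Coordinates are 1-based.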

Results

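Binding of FLAG-tagged Lbx1 was profiled by ChIP-seq in retinoic-acid-induced P19 neurons that carried either the wild-type protein or a frameshift form. Lbx1 is a homeodomain transcription factor of dorsal hindbrain and spinal cord interneurons. Each construct had 2 immunoprecipitated samples and 1 input, and each was represented by 1 peak list. The design asks which chromosomal sites are bound by both forms and which by only one of them. The samples include no anti-FLAG immunoprecipitate from cells without a tagged construct. Peaks that arise from the antibody or the chromatin, and not from Lbx1, therefore cannot be told apart from binding, also where both lists hold them. There were no replicate values, so each difference below is between these 2 lists, and the intervals cover counting error only. The read depth behind the lists is unknown, and a peak missing from a list may lie under its calling threshold.

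The frameshift list held 12342 peaks and the wild-type list 7356, a ratio of 1.68. Peaks were narrow in both lists, with a median width of 189 bp for wild-type and 199 bp for frameshift, and none exceeded 627 bp. The narrowest peaks were 188 bp in the wild-type list and 182 bp in the frameshift list, so the wild-type median lay almost at its minimum. Whether the caller set a minimum width is not given, so widths and covered length are not read as properties of the sites. Together the peaks covered 1.45 Mb in the wild-type list and 2.56 Mb in the frameshift list. The signal value ran from 0.368 to 1.82 with a median of 0.558 in the wild-type list. In the frameshift list it ran from 0.126 to 1.62 with a median of 0.205. How the signal was scaled between lists is not given in the sources used here, so these levels were not compared across lists. The maximum score of 1000 was held by 72.9% of wild-type peaks (95% Wilson interval 71.9 to 73.9%) and by 86.0% of frameshift peaks (85.4 to 86.6%).

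More than every second wild-type site was also a frameshift site. Of the 7356 wild-type peaks, 4343 overlapped a frameshift peak, or 59.0% (57.9 to 60.2%), and 3013 did not. Of the 12342 frameshift peaks, 4344 overlapped a wild-type peak, or 35.2% (34.4 to 36.0%), and 7998 did not. Shifted positions gave far less: over 1000 circular shifts of the frameshift list, 0.0544 to 0.367% of wild-type peaks were overlapped, with a mean of 0.201%. The summits of shared sites lay close together. Over the 4344 overlapping pairs the summits lay a median of 13 bp apart, 95% of pairs lay within 54 bp, and 98.5% lay within 100 bp (98.1 to 98.8%). The largest distance was 228 bp. Narrow peaks that overlap cannot have distant summits, so part of this closeness is built in, and no expected distance was computed.

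The strongest wild-type sites were nearly all present in the frameshift list, and the weak ones mostly were not. Among the 100 strongest wild-type peaks 97 were shared, among the 500 strongest 474, and among the 1000 strongest 926, or 92.6% (90.8 to 94.1%). When the list was divided into 10 equal parts by signal, the shared share fell from 93.9% (91.9 to 95.4%) in the strongest part to 30.5% (27.3 to 33.9%) in the weakest. The frameshift list showed the same order at lower levels. Of its 100 strongest peaks 94 were shared, of its 500 strongest 411, and of its 1000 strongest 734, or 73.4% (70.6 to 76.0%). Its shared share fell from 70.5% (67.9 to 73.0%) in the strongest of 10 parts to 15.2% (13.3 to 17.3%) in the weakest. These shares depend on the length of the other list. With the frameshift list restricted to its 7356 strongest peaks, 45.3% (44.2 to 46.5%) of the peaks of either list were shared.

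**Figure D1:**
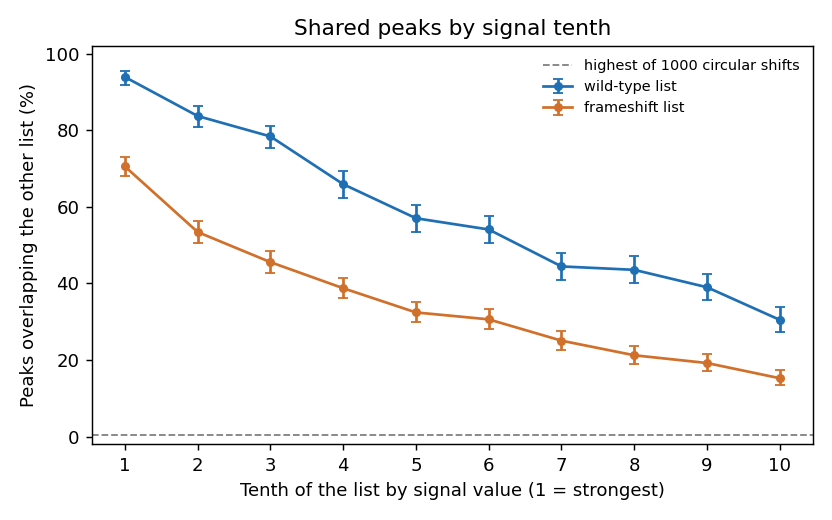
Percentage of peaks that overlap the other list by at least 1 bp (vertical axis), for 10 equal parts of each list from the strongest to the weakest signal value (horizontal axis); points are shares with 95% Wilson intervals, and the dashed line is the highest value over 1000 circular shifts. The wild-type list falls from 93.9 to 30.5% and the frameshift list from 70.5 to 15.2%.

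Shared peaks had higher signal values than list-specific peaks within each list. In the wild-type list the median was 0.642 for shared peaks (quartiles 0.506 and 0.832) and 0.488 for wild-type-only peaks (0.428 and 0.579), a difference of 0.154 (bootstrap interval 0.144 to 0.165). In the frameshift list the median was 0.261 for shared peaks (0.192 and 0.387) and 0.187 for frameshift-only peaks (0.155 and 0.247), a difference of 0.0737 (0.0683 to 0.0791). The ranges of shared and list-specific peaks overlapped widely in both lists. The maximum score was held by 82.0% of shared and 59.8% of wild-type-only peaks in the wild-type list, and by 93.4% of shared and 82.0% of frameshift-only peaks in the frameshift list.

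Sites that ranked high for one form tended to rank high for the other, with much scatter. Over the 4344 shared pairs, Spearman's rho between the signal values was 0.44 (bootstrap interval 0.42 to 0.47). It is a correlation across peaks, which are not independent replicates. Of the 1000 strongest peaks of each list, 404 were paired with a peak among the 1000 strongest of the other, or 40.4% (37.4 to 43.5%).

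**Figure D2:**
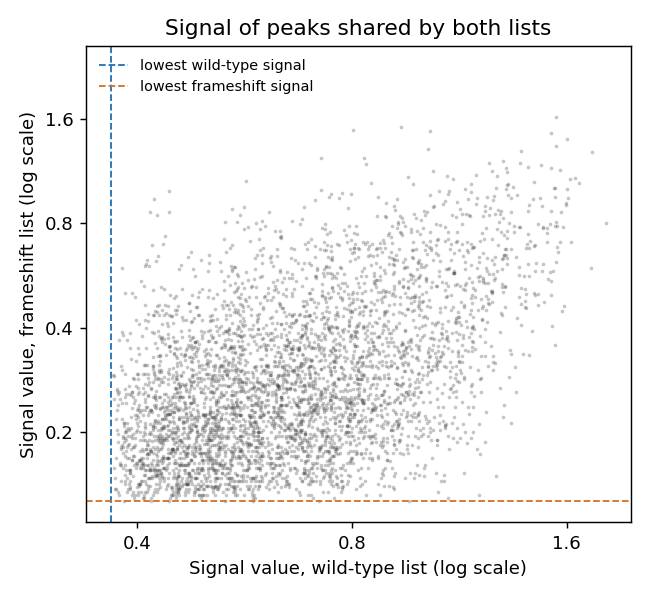
Signal value of each of the 4344 pairs of overlapping peaks in the wild-type list (horizontal axis, log scale) and the frameshift list (vertical axis, log scale), in the lists' own units, with dashed lines at the lowest listed signal of each list. The points rise together with wide scatter (Spearman's rho 0.44).

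The strongest shared site of the wild-type list lay at chr13:18247856-18248047, with a signal of 1.82 in the wild-type list and 0.800 in the frameshift list, where it ranked 163. The next lay at chr13:100529117-100529311, with signals of 1.74 and 1.29 and a frameshift rank of 10. The third, at chr9:48770219-48770407, had signals of 1.73 and 0.595 and a frameshift rank of 504. The others among the 10 strongest were at chr6:51948943-51949131, chr18:83713328-83713586, chr11:16034547-16034734, chr13:39615823-39616010, chr2:160329677-160329864, chr11:35108742-35108929 and chr4:31965639-31965844. All 10 had wild-type signals between 1.601 and 1.816, and 7 of the 10 ranked among the 100 strongest frameshift peaks. The site at chr4:31965639-31965844 ranked 10 in the wild-type list and 6 in the frameshift list. The strongest frameshift peak of all, at chr12:92651245-92651435 with a signal of 1.62, overlapped the wild-type peak of rank 24. The others of the 10 strongest frameshift peaks, in order, overlapped wild-type peaks of rank 778, 1359, 517, 33, 10, 22, 535, 84 and 2.

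The strongest wild-type-only peak ranked 82 in its list. It lay at chr4:73150152-73150339 with a signal of 1.39, and a frameshift peak ended or began 77 bp from it without overlapping. The second lay at chr16:39151880-39152067 with a signal of 1.37, and the nearest frameshift peak was 46.8 kb away. The third, at chr1:28201711-28201898, had a signal of 1.36 and its nearest frameshift peak 438.9 kb away. The fourth, at chr12:6629591-6629778, had a signal of 1.25 and its nearest frameshift peak 661.7 kb away. The remaining 6 of the 10 strongest were at chr18:50556855-50557060, chr9:13391988-13392175, chr5:104367809-104367997, chr10:125060986-125061173, chr3:58232948-58233135 and chr13:109335428-109335615. Their signals were between 1.20 and 1.24, and the one on chromosome 5 lay 6 bp from a frameshift peak.

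The strongest frameshift-only peak ranked 19 in its list. It lay at chr7:59009552-59009751 with a signal of 1.16, 22 bp from a wild-type peak. The second, at chr10:91094222-91094403, had a signal of 1.13 and a wild-type peak 2.49 kb away. The third lay at chr13:7056758-7056957 with a signal of 1.03 and the fourth at chr18:42798458-42798656 with a signal of 1.02, with the nearest wild-type peaks at 20.6 and 101.1 kb. The remaining 6 of the 10 strongest were at chr13:103499745-103499933, chr3:103512454-103512644, chr6:12008886-12009097, chr6:51742590-51742801, chr15:75650030-75650216 and chr12:28477844-28478032. Their signals were between 0.863 and 0.985, and the one on chromosome 15 had its nearest wild-type peak 1334 kb away.

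Peaks of both forms were gathered in the same chromosomal regions. In 1 Mb windows the densest was 55 to 56 Mb of chromosome 18, with 32 wild-type and 49 frameshift peaks, against means of 2.79 and 4.68 per window. The next were 18 to 19 Mb of chromosome 11 with 28 and 44 peaks, 115 to 116 Mb of chromosome 2 with 23 and 38, 132 to 133 Mb of chromosome 5 with 24 and 35, and 52 to 53 Mb of chromosome 6 with 22 and 36. When peaks were spread at random over each chromosome 1000 times, no window held more than 16 wild-type or 21 frameshift peaks. Above these limits were 8 windows of the wild-type list and 29 of the frameshift list, and all 8 were among the 29. Shared sites enter the counts of both lists, so part of this agreement is built in. The random placements took no account of regional differences in copy number or mapping. The wild-type peaks that were shared numbered 24 of 32 in the window on chromosome 18, 18 of 28 in that on chromosome 11, 13 of 23 on chromosome 2, 22 of 24 on chromosome 5 and 20 of 22 on chromosome 6. In the other 3 of the 8 windows they numbered 15 of 18 at 54 to 55 Mb of chromosome 18, 16 of 17 at 27 to 28 Mb of chromosome 8 and 7 of 17 at 35 to 36 Mb of chromosome 11.

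Across autosomes the lists kept nearly the same proportions. The ratio of wild-type to frameshift peaks was 0.596 over all and ranged from 0.536 on chromosome 17 to 0.655 on chromosome 12 among the 19 autosomes. On the X chromosome, with few peaks, it was 0.697. Among the autosomes chromosome 11 had the highest density in both lists, with 4.18 wild-type and 6.92 frameshift peaks per Mb. The X chromosome had far fewer peaks, 99 in the wild-type and 142 in the frameshift list, or 0.595 and 0.853 per Mb, where the autosomes had 2.95 and 4.95. Its density was 0.202 of the autosomal density in the wild-type list (exact interval 0.164 to 0.246) and 0.172 in the frameshift list (0.145 to 0.203). On the X chromosome 51 of 99 wild-type peaks were shared, or 51.5% (41.8 to 61.1%), an interval that includes the 59.0% of the whole list.

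**Figure D3:**
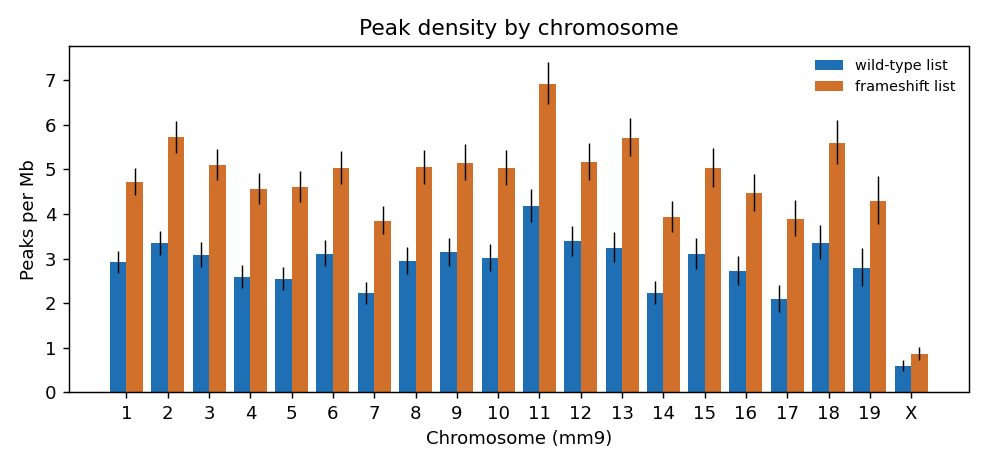
Peaks per Mb (vertical axis) on each mm9 chromosome (horizontal axis) in the wild-type and frameshift lists; bars are counts divided by the position of the last peak, with exact 95% Poisson intervals. Among the autosomes and the X chromosome, chromosome 11 is highest in both lists (4.18 and 6.92) and the X chromosome lowest (0.595 and 0.853).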

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

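Of 32 values recomputed under alternative settings, 25 stayed within the interval of the reported value (or within 1.5 times of a count), and 7 moved. A change of direction was checked only for the differences of median signal, and none changed direction. Restriction to the maximum score, equal list lengths, the stronger part of each list and removal of the densest windows were chosen after seeing the data. With peaks within 1 kb counted as shared, 61.4% of wild-type and 37.7% of frameshift peaks were shared. With only peaks at the maximum score in both lists, the shares were 62.7% and 31.6%. With the frameshift list at the length of the wild-type list, both were 45.3%, the loss for wild-type peaks following from the shorter list. Without the top 1% of peaks of either list, Spearman's rho between signal values was 0.39, and the cause was not tested. Reciprocal overlap of 50%, summits within 100 bp, the stronger part of each list, and removal of unplaced sequences or of the densest windows moved neither share beyond its interval. Removal of peaks wider than 2 kb tested nothing, since there were 0 such peaks, and its values are among the 25. Removal of unplaced sequences left 7354 wild-type and 12337 frameshift peaks, so it could hardly move a share or a count. Summits within 100 bp could hardly move a share either, since 98.5% of overlapping pairs had them. The tolerance for counts was wide: restriction to the maximum score left 5362 wild-type and 10618 frameshift peaks, and these counts are among the 25. The planned q-value and fold-enrichment thresholds could not be applied, because the lists hold neither, and medians of the score were not compared in place of q because most peaks are at its maximum. Among peaks at the maximum score in both lists, the shared minus list-specific difference of median signal was 0.155 in the wild-type and 0.0790 in the frameshift list, within the intervals of the reported values. The analyses of genes, promoters and motifs were not run without an mm9 reference. No paired analysis was possible because each construct has 1 list and no values per replicate, and for the same reason no replicate could be left out. Read depth is unknown, so absence of a peak from a list cannot be read as absence of binding.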

Other observations

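The first test on frameshift peaks without a partner and both tests on the X chromosome were written after the results they bear on had been seen, and the windows and distances were also chosen then.

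Peaks found in only one list lay near peaks of the other list more often than under circular shifts. Of the 3013 wild-type-only peaks, 18.1% (16.8 to 19.5%) lay within 10 kb of a frameshift peak, where 1000 circular shifts gave 6.90 to 10.3%. Of the 7998 frameshift-only peaks, 13.6% (12.9 to 14.4%) lay within 10 kb of a wild-type peak, where shifts gave 4.51 to 6.43%. Within 50 kb the shares were 44.1% and 38.5%, against at most 34.7% and 24.4% under shifts. Part of the excess is near misses of the 1 bp overlap rule. Counting peaks within 1 kb as shared raised the shared share from 59.0 to 61.4% of wild-type peaks and from 35.2 to 37.7% of frameshift peaks. Counts of wild-type-only and frameshift-only peaks per 1 Mb window were correlated, with Spearman's rho of 0.32 across 2638 windows, where shifts by whole windows gave at most 0.13. Windows are not independent replicates. Neither kind of shift took account of regional differences in copy number or mapping. The excess over shifts therefore cannot tell regions bound by both forms from such differences. Wild-type peaks made up 37.3% of all peaks of both lists, and their share was compared among 140 windows with at least 20 peaks. The lowest share was 2 of 21 peaks, 9.52% (1.17 to 30.4%), at 97 to 98 Mb of chromosome 5, and the highest was 13 of 20, 65.0% (40.8 to 84.6%), at 44 to 45 Mb of chromosome 13. These are the extremes of the 140 windows. The interval left out 37.3% in 4 windows, 2 below and 2 above, where 4.11 would be expected from independent counts at these window sizes. Shared sites enter both counts and draw the shares together, so this tally neither shows nor excludes an excess.

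Strong frameshift peaks lacked a wild-type partner more often than strong wild-type peaks lacked a frameshift partner. With both lists at 7356 peaks, 22.4% (19.6 to 25.6%) of the strongest 735 frameshift peaks and 10.1% (8.10 to 12.5%) of the strongest 735 wild-type peaks had none, a gap of 12.4 percentage points that argues against unequal list length as the whole cause. In the full frameshift list 364 of the strongest 1235 peaks had no partner, and 2.47% (1.31 to 4.63%) of these lay within 1 kb of a wild-type peak, which argues against one site called as neighbouring peaks. Of the 871 wild-type partners, 1.03% (0.545 to 1.95%) lay in the weakest of 10 parts of the wild-type list. These parts hold equal numbers of peaks, and the weakest lies between the lowest signal of 0.368 and the lower quartile of 0.459. Signals in the list reach 1.82, so few partners in this narrow span cannot decide whether others lie below the wild-type signal floor. Partners below that floor thus stay open. Filters of the caller other than signal, unequal depth or enrichment of the samples, and a difference in binding between the constructs also stay open. They were not tested, since no values per replicate or read counts were used here.

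The X chromosome carried few peaks of either form. If these cells held a single X for each pair of autosomes, peak number might fall in proportion. The upper bound of the X to autosome density ratio was at most 0.246 over both lists, under the 0.5 that this needs. Peaks are called above a threshold, so their number need not follow copy number. The ratio thus speaks only against a proportional fall and does not decide whether a single X contributed. A single copy could also halve each peak's signal. Then 24.8% of wild-type and 33.9% of frameshift autosomal peaks would stay above their list's lowest signal. In the wild-type list the observed ratio was 0.202 (0.164 to 0.246), with an upper bound just under the expected 0.248. In the frameshift list it was 0.172 (0.145 to 0.203), or 0.508 of the expectation. The expectation assumes a linear signal scale, which no source states, and that X peaks follow the autosomal signal profile, so this remains undecided, as do gene content and unequal mapping of the X chromosome. Median signal values on the X chromosome and the autosomes were 0.506 and 0.558 in the wild-type list, and 0.176 and 0.206 in the frameshift list.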
